A study of Mus musculus with 8 samples.

How the data were processed

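Total RNA from spleen cells of leukemic mice was biotin-labelled and hybridised to Affymetrix mouse expression arrays, per the labels' protocols. The labels give 8 arrays, 4 per genotype, from 2 animals per genotype, with 1 array for animal 1 and 3 arrays for animal 2. The full-length mice carried the leukemia fusion CBFb-SMMHC and were sampled 2 months after treatment with the mutagen ENU. The truncated mice expressed CBFb-SMMHCd179-221, which lacks a stretch of the fusion, and were sampled 3 weeks after birth. Mutagen, age and genotype therefore go together, and no fit could separate them. The sample labels call the mice of both genotypes chimeras, whereas the series text describes the full-length mice as knock-in, so the share of cells that carried each fusion is not known here.

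The deposited table holds 45101 probe sets for the 8 arrays in log2 units. The submitters' processing notes name RMA, with no version, and the log base was read from the range of the values because the sources used here do not give it. RMA subtracts background, normalizes quantiles and summarises probes, so values of dim probe sets are drawn together and the differences of dim genes are understated. The table holds no detection calls here, and a low value was not read as absence. For arrays, their number limits the precision.

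Probe sets were named through the platform annotation, in which 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none, with 64 control probe sets apart. Of the 18195 gene identifiers of probe sets with 1 gene, 18033 were found in the table of the GRCm38.p6 annotation, and 0 symbols needed an update. Probe sets with several genes or none were left out. Probe sets whose identifier ends in s_at or x_at can match related sequences, which applies to those of Mllt3, Rrm2, Xist, Ighm, Slc4a1, Hdc, Ms4a6d and Clec4n, and to some of the other probe sets given for Tgfa and Galnt2.

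The animal was the unit of replication. The labels do not say whether the arrays of an animal were separate extractions. They were averaged, each gene was represented by its probe set with the highest mean, and a gene was kept where at least 2 of the 4 animals lay above the median over all probe sets. This left 11392 genes. The genotypes were compared on log2 values with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 2 residual degrees of freedom, 3.24 prior degrees of freedom and Benjamini-Hochberg adjusted p under 0.05. Values are given as mean ± SD over the 2 animals of a genotype, and differences are truncated minus full-length. An exact permutation test of 2 animals against 2 cannot go below 0.333 (two-sided), so no such p is given for single genes.

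A total of 35 gene lists were written from textbook knowledge before the data were examined, with markers of other spleen cell types among them. Of their 660 symbols, 600 were on the array, and 45 stood in more than 1 list. The 31 lists with at least 5 measured members were tested with camera of limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. The test was repeated with an estimated correlation, and with fry, a rotation test of whether a list's genes move one way. With an estimated correlation camera rests on the 2 residual degrees of freedom and has little power. The monocyte and macrophage list had an estimated correlation of -0.037, below the preset one. Its unadjusted camera p still rose from 4.34e-18 to 0.0110. A list that did not pass with an estimated correlation was therefore not read as unshifted. The adhesion (-0.022) and ribosome biogenesis (-0.0016) lists also lay below the preset correlation. The other called lists lay above it, with 0.920 for primary granule, 0.799 for erythroid and 0.352 for secondary granule genes. Plasma cell genes had 0.331, RUNX1 and CBF targets 0.133 and B cell genes 0.113. For lists whose genes vary together that much, the preset correlation gives p-values that are too small. Members were also adjusted over the list alone. Which 18 lists are described one by one was chosen after their values were seen.

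The rule for named genes was also set beforehand. It took Cbfb, Myh11 and Runx1 in any case. It took the 10 genes per direction with the largest difference among those past the threshold, or with the smallest p where none passed. It took up to 4 passing members of each described list, or the 2 with the largest differences where none passed, and Xist and Y-linked genes as values. Unnamed clones and immunoglobulin or T cell receptor segments were left out. Other genes named below were chosen after their values were seen, and the text says so.

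The fits were tested on simulated data in 20 runs for the comparison of 2 animals against 2, with 200 of 11392 genes changed. At an adjusted p of 0.05, 0.9% of genes changed by 1 log2 unit were found, 48.3% of those changed by 2, 85.2% by 3 and 93.3% by 4. The mean number of calls was 119.25, of which 5.4 were false. A simulated list shift was found in 20 of 20 runs, with 0 of 380 unshifted lists called. The noise was drawn independently for each gene, so these rates do not carry over to lists whose genes vary together. In the real data, the 2 splits of the animals that cut across genotype called 10 and 8 lists with the preset correlation.

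The alternatives were an intensity trend with a robust prior, other filters on dim genes, centring or quantile normalization of the arrays, other units of replication, a block for the animal or array number, other choices of probe set, other thresholds and set tests, and leaving out each animal and each array of animal 2. A further 3 alternatives on the grouping of arrays, and the estimated correlation in the other settings, were added after the data were seen. Figures were drawn with matplotlib 3.10.9.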

Results

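The series profiled gene expression in spleen cells from leukemic mice that expressed either of 2 forms of the CBFb-SMMHC fusion protein, which joins the core-binding factor subunit CBFb to the tail of smooth muscle myosin heavy chain. One form was full-length, and the other, CBFb-SMMHCd179-221, lacked a segment that contributes to high-affinity binding of RUNX1. Each genotype had 4 arrays from 2 animals, with 1 array for animal 1 and 3 for animal 2. The median log2 expression of the 8 arrays lay between 4.71 and 4.77. The comparison asks how leukemic spleen cells with the truncated fusion differ in expression from those with the full-length fusion.

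Genes of the neutrophil granules and of monocytes were higher in spleen cells with the truncated fusion, while ribosome biogenesis and erythroid genes were lower. Leaving out 2 full-length arrays that were high in erythroid genes was tried after the data were seen, and left only animal 2 among the full-length mice. The erythroid list then turned direction, and the median difference of the ribosome biogenesis list went from -0.34 to -0.20. The median difference went from 2.66 to 0.94 for the primary and from 2.52 to 1.42 for the secondary granule list. Ltf (lactoferrin, a protein of the secondary granule) was at 7.04 ± 1.32 in full-length and 11.23 ± 0.28 in truncated animals (log2, SD, n = 2 animals each), a difference of 4.20, which was 2.31 without these 2 arrays. Mpo (myeloperoxidase of the primary granule) was at 7.33 ± 2.49 and 12.08 ± 0.23, with full-length arrays at 5.57 and 4.86 on one side and 11.17 and 11.25 on the other, and its difference of 4.75 was 0.87 without the former 2 arrays. The macrophage gene Mrc1 was at 5.36 ± 0.91 and 8.23 ± 0.07. These list shifts passed camera with a preset correlation between genes but not with an estimated correlation (adjusted p = 0.340 to 0.856), and no single gene passed over all genes. With 2 residual degrees of freedom, camera with an estimated correlation has little power. The preset correlation of 0.01, in turn, gives p-values that are too small for lists whose genes vary together. The estimated correlation was 0.920 for the primary granule, 0.799 for the erythroid and 0.352 for the secondary granule list. It was -0.037 for the monocyte and -0.0016 for the ribosome biogenesis list.

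Among single genes, Cxcl12 (a chemokine that holds blood progenitors in their niche) had the smallest p of those with a higher value in truncated animals. Its log2 expression was 4.18 ± 0.11 in full-length and 8.33 ± 0.33 in truncated animals, 17.8-fold apart (limma, adjusted p = 0.0669). Sphk1 (sphingosine kinase) lay in the opposite direction, at 9.90 ± 0.22 and 5.68 ± 0.17, 18.7-fold apart by its brightest probe set (limma, adjusted p = 0.0669), while another probe set differed by -1.12. The other 9 genes with the smallest p and a higher value in truncated animals were the neutrophil collagenase Mmp8 (difference 2.63), the interferon-inducible genes Ifi209 (3.67) and Ifitm1 (3.07), As3mt (2.58), Rnpep (2.77), the mitochondrial transhydrogenase Nnt (2.91), the G protein subunit Gnaq (2.43), Galnt2 (2.80) and Nucb2 (2.50). The other 9 with a lower value were Padi3 (-3.83), the growth factor Tgfa (-3.02), the mast cell tryptase Tpsab1 (-2.35), Mllt3 (-3.33), Hoxc4 (-2.78), the chloride channel Clcn2 (-1.77), Rgs12 (-1.97), the transcription factor Gata3 (-2.19) and Camsap3 (-1.72). Each of these 18 genes had an adjusted p of 0.0822 and did not pass. Other probe sets of Tgfa differed by only -0.17 and -0.05, another of Ifi209 by 0.77, others of Gnaq by 0.87 and 1.54, another of Galnt2 by 1.45 and another of Mllt3 by -1.88, so the size of these differences depends on the probe set. The arrays of the genotypes did not overlap for any of the 20 genes, as the plot of these genes per array shows. The choice by smallest p favours such genes, so this adds no support. In full-length animals 5 of the 10 higher genes, Cxcl12 among them, and in truncated animals 3 of the 10 lower genes lay below 4.74, the median of the array medians, so their folds rest on dim values.

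**Figure D1:**
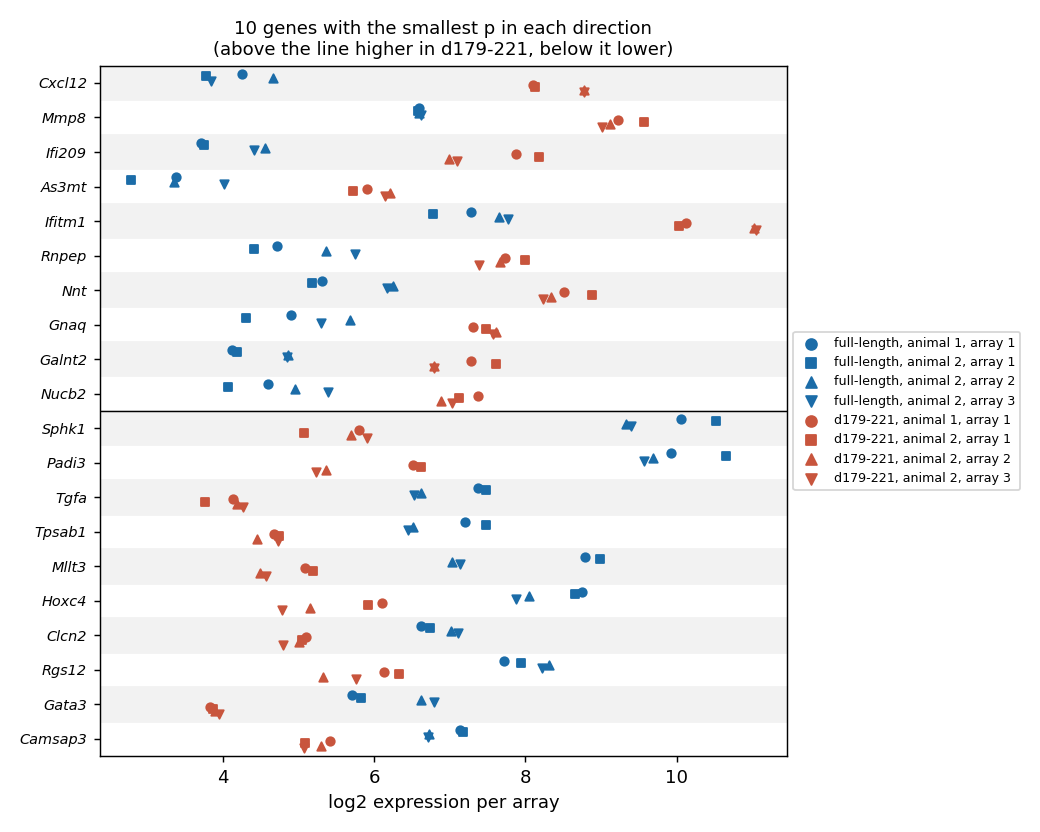
Log2 expression (x axis) of the 20 genes with the smallest p, 1 point per array, coloured by genotype and shaped by animal and array. The 4 arrays of each genotype lie apart for all 20 genes, and none of the genes passed the adjusted p of 0.05.

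Over all 11392 genes tested, 0 were higher and 0 were lower at an adjusted p under 0.05 in limma, and 187 were higher and 22 lower under 0.10. At an unadjusted p under 0.05 the counts were 1000 higher and 605 lower. The arrays of the genotypes did not overlap for 1171 genes with higher and 997 with lower values, 19.03% of the genes. Independent arrays would give 2.86% by chance, but arrays of an animal are not independent, and parting the array of animal 1 and array 1 of animal 2 from arrays 2 and 3 in both genotypes gave 19.18%. The count under 0.05 depended on single arrays. It was 291 higher and 41 lower without array 2 of full-length animal 2, and 376 and 46 without its array 3. Without array 2 or array 3 of truncated animal 2 it was 1 and 1.

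Of the genes of the fusion and its binding partner Runx1, Cbfb was at 9.88 ± 0.38 in full-length and 9.42 ± 0.02 in truncated animals (limma, adjusted p = 0.543). Its probe set is not known here to lie in the deleted part, so the value does not check the genotype labels. Both Myh11 probe sets were dim, with means of 3.26 to 3.84 per genotype, and were not tested. Runx1 was at 7.51 ± 1.01 and 7.02 ± 0.10 by its brightest probe set (limma, adjusted p = 0.759). Its direction depended on the probe set, as others differed by 0.12, 0.084, 0.33 and 0.085, and a further one by -0.67. Within full-length animals Runx1 lay at 6.79 and 6.41 in the array of animal 1 and array 1 of animal 2, and at 9.11 and 9.15 in arrays 2 and 3 of animal 2.

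The primary granule and promyelocyte list, genes of the azurophil granule and its precursors, had 14 measured members, all with a higher value in truncated animals. Its median difference was 2.66 (camera of limma, adjusted p = 2.56e-11), and adjusted p = 0.662 with an estimated correlation. Of the 14, 12 passed when adjusted over the list alone and 0 over all genes. The protease Ctsg was at 6.24 ± 3.19 in full-length and 11.34 ± 0.07 in truncated animals, with an adjusted p of 0.217 in limma. In full-length arrays Ctsg lay at 3.99 and 4.54 in the array of animal 1 and array 1 of animal 2, and at 10.48 in arrays 2 and 3. The same 2 full-length arrays were high in erythroid genes, with list medians of 11.0 and 11.2 against 8.62 and 8.64 in arrays 2 and 3. Without these 2 arrays, which was tried after the data were seen and leaves only animal 2 among the full-length mice, the median difference of the primary granule list was 0.94. The list median was 9.26 and 9.31 in full-length arrays 2 and 3. It was 9.20 in the array of truncated animal 1 and 9.25 in array 1 of truncated animal 2. Only arrays 2 and 3 of truncated animal 2 lay higher, at 10.46 and 10.49.

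The secondary and tertiary granule list, genes of later neutrophil stages, had 20 measured members, of which 19 had a higher value in truncated animals. Its median difference was 2.52 (camera of limma, adjusted p = 6.72e-17), and adjusted p = 0.583 with an estimated correlation. Of these members, 19 were higher and 1 lower when adjusted over the list alone, and 0 passed over all genes. The member with the lower value was the cytokine gene Il1b (-1.97), named after its value was seen. The cathelicidin gene Camp was at 6.91 ± 1.29 and 11.00 ± 0.13, with an adjusted p of 0.0826 in limma. Ltf had an adjusted p of 0.0826 and lay between 6.06 and 8.94 in the full-length arrays and between 11.03 and 11.57 in the truncated arrays. Without the 2 full-length arrays high in erythroid genes, which leaves only animal 2 among the full-length mice, the median difference of the list was 1.42.

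The monocyte and macrophage list had 20 measured members, all with a higher value in truncated animals. Its median difference was 1.61 (camera of limma, adjusted p = 6.72e-17), and adjusted p = 0.340 with an estimated correlation. It was also called by fry (adjusted p = 0.0126). When adjusted over the list alone 17 passed, and over all genes 0 did. The list median of the animals was 6.84 ± 0.03 in full-length and 8.32 ± 0.07 in truncated animals. Vcam1, an adhesion molecule of splenic macrophages and endothelium, was at 5.15 ± 1.44 and 8.88 ± 0.34, with an adjusted p of 0.107 in limma. Mrc1, the mannose receptor, had an adjusted p of 0.0851. Without the 2 full-length arrays high in erythroid genes, which leaves only animal 2 among the full-length mice, the median difference of the list was 1.34.

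**Figure D2:**
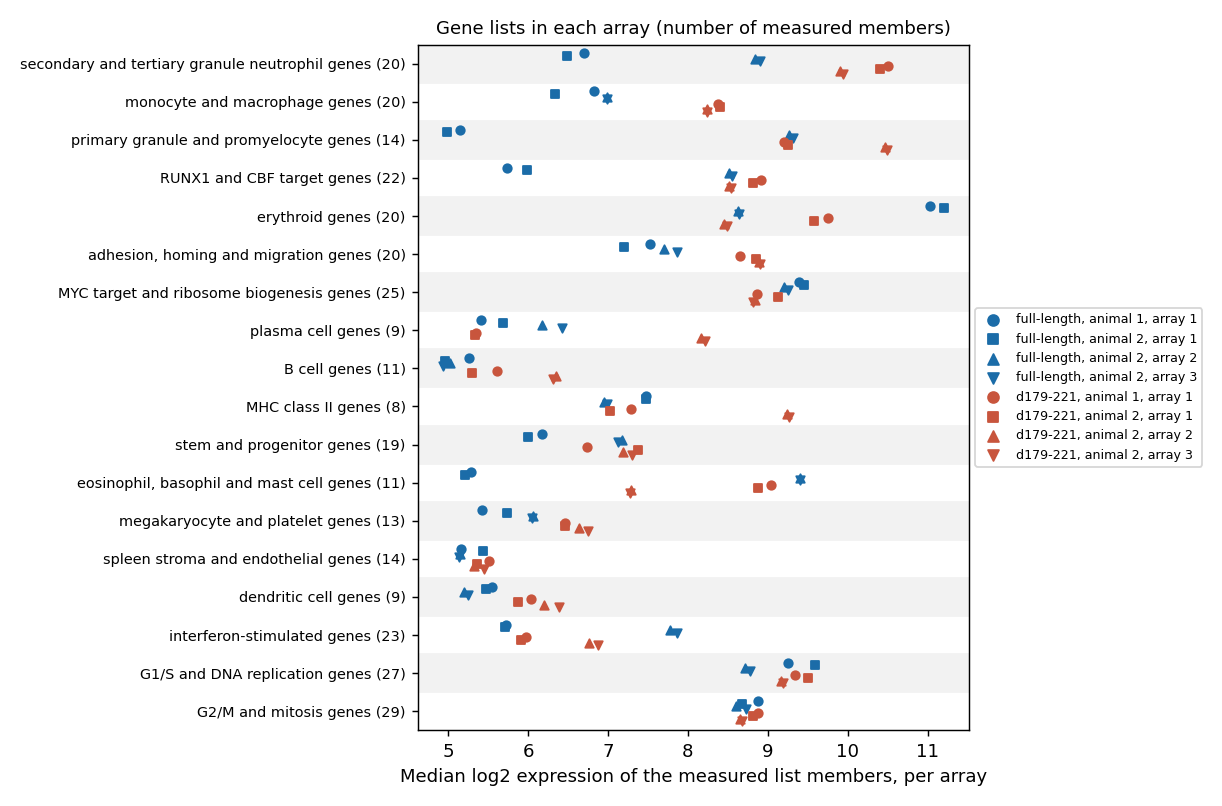
Median log2 expression (x axis) of the measured members of 18 gene lists, 1 point per array, coloured by genotype and shaped by animal and array. Granule lists are low and the erythroid list is high in the array of full-length animal 1 and in array 1 of full-length animal 2. The 4 arrays of each genotype lie apart in the monocyte and macrophage list. They also lie apart in other lists, among them the secondary granule and the adhesion lists.

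The list of RUNX1 and CBF target genes had 22 measured members, of which 13 also stand in another list. In truncated animals 19 had higher and 3 had lower values. Its median difference was 0.80 (camera of limma, adjusted p = 1.88e-06), and adjusted p = 0.619 with an estimated correlation. Adjusted over the list alone 8 were higher and 1 was lower, and over all genes 0 passed. The members with the largest differences were Ctsg (5.09) and Mpo (4.75), which also stand in the primary granule list. The member that was lower was Nfe2 (-1.05), a transcription factor of megakaryocytes and erythroid cells, named after its value was seen. The list median was 5.73 and 5.99 in the 2 full-length arrays high in erythroid genes, and between 8.51 and 8.91 in the other 6 arrays. Without these 2 arrays, which leaves only animal 2 among the full-length mice, the median difference was 0.69.

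The erythroid list had 20 measured members, of which 19 had a lower value in truncated animals. The median of their differences was -0.83 (camera of limma, adjusted p = 0.000496), and adjusted p = 0.856 with an estimated correlation. No member passed, either adjusted over the list alone or over all genes. Trim10 was at 9.20 ± 0.89 in full-length and 7.06 ± 0.27 in truncated animals, and Ank1, the red cell ankyrin, at 9.64 ± 1.93 and 8.25 ± 0.82. The direction rested on the array of full-length animal 1 and array 1 of full-length animal 2. Without animal 1 the median was -0.04 (adjusted p = 0.416) and without array 1 of animal 2 it was -0.45 (adjusted p = 0.0790). Without both arrays, which leaves only animal 2 among the full-length mice, the list median was higher in truncated animals by 0.46. The call also ended with the animal as a random block on 8 arrays (-0.55, adjusted p = 0.0578).

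The adhesion, homing and migration list had 20 measured members, 13 with higher and 7 with lower values in truncated animals. Its median difference was 0.99 (camera of limma, adjusted p = 0.000496), and adjusted p = 0.544 with an estimated correlation. Of the members, 9 passed when adjusted over the list alone, all with higher values, and over all genes 0 did. Cxcr4, the receptor of Cxcl12, was at 5.14 ± 0.57 in full-length and 7.58 ± 0.25 in truncated animals, with an adjusted p of 0.0826 in limma. Vcam1, the other member with a large difference, stands in the monocyte list as well.

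The list of MYC targets and ribosome biogenesis had 25 measured members, of which 24 had a lower value in truncated animals. The median difference was -0.34 (camera of limma, adjusted p = 0.000763), and adjusted p = 0.544 with an estimated correlation. No member passed, either adjusted over the list alone or over all genes. The helicase gene Ddx21 was at 9.34 ± 0.20 and 8.43 ± 0.45, and Polr1b, a subunit of RNA polymerase I, at 8.05 ± 0.31 and 7.29 ± 0.16. Without the 2 full-length arrays high in erythroid genes, the median difference was -0.20, against -0.22 without animal 1 of the full-length or animal 2 of the truncated mice, and in the first case the list did not pass (camera of limma, adjusted p = 0.165).

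The proliferation lists did not pass on the animal means. The 27 measured genes of G1/S and DNA replication had a median difference of 0.02 (camera of limma, adjusted p = 0.488), with Rrm2 at 9.80 ± 0.38 and 10.64 ± 0.14 and Pola1 at 8.04 ± 0.57 and 8.76 ± 0.10. It passed without full-length animal 1 (0.22, adjusted p = 0.00744), without the 2 full-length arrays high in erythroid genes (0.45, adjusted p = 4.76e-05) and on 8 arrays with a block for the animal and array number (0.12, adjusted p = 0.0380). In these settings the list had an adjusted p of 0.705 or more with an estimated correlation. The 29 genes of G2/M and mitosis had a median difference of 0.03 (adjusted p = 0.906), with Ube2c at 10.05 ± 0.73 and 9.47 ± 0.49 and Birc5 at 9.27 ± 0.10 and 9.64 ± 0.07.

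The plasma cell and B cell lists passed camera on the animal means, with values that differed between the arrays of a genotype. All 9 measured plasma cell genes had a higher value, with a median difference of 0.58 (camera of limma, adjusted p = 0.0241) and adjusted p = 0.717 with an estimated correlation. Adjusted over the list alone 0 passed. Mzb1, a chaperone of antibody-secreting cells, was at 4.86 ± 0.21 and 5.88 ± 0.83, and Edem1 at 7.78 ± 0.53 and 8.78 ± 0.49. The plasma cell list median was 8.16 and 8.21 in arrays 2 and 3 of truncated animal 2 and 5.34 in each of the other 2 truncated arrays, which lay below all 4 full-length arrays (5.41 to 6.43), and without truncated animal 2 the adjusted p of the list was 0.914. The call also ended without either full-length animal (adjusted p = 0.0826 and 0.0746) without array 2 or 3 of truncated animal 2 (0.0539 and 0.0668), without the 2 full-length arrays high in erythroid genes (0.146), with an intensity trend and robust prior (0.0747) and with 1 array per animal (0.920). Of 11 measured B cell genes 9 had a higher value, with a median difference of 0.39 (camera of limma, adjusted p = 0.0241) and adjusted p = 0.662 with an estimated correlation. Adjusted over the list alone 3 passed, of which Cd79b, a part of the B cell receptor, was at 5.39 ± 0.18 and 6.73 ± 0.34, and the other two were Bank1 (1.25) and Blnk (1.23), named after their values were seen. Over all genes 0 of either list passed, and Tnfrsf13c, the receptor of the survival factor BAFF, had a difference of -1.27. The B cell call ended without animal 2 of the truncated (adjusted p = 0.517) or full-length mice (0.337), and without array 2 or 3 of the former (0.0624 and 0.0668) or array 3 of the latter (0.0526), and with 1 array per animal (0.920).

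The lists of other cell types did not pass camera on the animal means, and several passed in other settings. The 8 MHC class II genes had a median difference of 0.14 (camera of limma, adjusted p = 0.147), with H2-Oa at 5.93 ± 0.30 and 7.71 ± 0.24 and H2-DMa at 6.47 ± 0.03 and 7.63 ± 0.48. Adjusted over the list alone both of these passed, and the list passed without truncated animal 1 (median 0.96, adjusted p = 1.29e-05) and without array 1 of truncated animal 2 (0.57, adjusted p = 0.0349) or of both genotypes (0.78, adjusted p = 0.0158). It also passed with best-correlated arrays as units (adjusted p = 0.0475) and with 8 arrays taken as independent (0.0470). The 9 dendritic cell genes had a median difference of 0.23 (adjusted p = 0.0553), with Tcf4 at 6.22 ± 0.99 and 7.37 ± 0.02 and Ly6d at 4.73 ± 0.10 and 5.58 ± 0.41. This list passed without animal 1 of the full-length (adjusted p = 0.0169) or truncated mice (0.00501), without array 1 of animal 2 of either (0.0244 and 0.0188) or both (0.00663), and without the 2 full-length arrays high in erythroid genes (0.0146). It passed as well with other choices of probe set (0.0112 for their mean and 0.0331 for the most variable), and on 8 arrays with the animal as a random block (0.0369), with the animal and array number as a block (0.0118), taken as independent (0.00623) or paired by best correlation (0.00818). The 13 megakaryocyte and platelet genes had a median difference of 0.43 (adjusted p = 0.101), with the tetraspanin Cd9 at 5.42 ± 0.24 and 7.17 ± 0.18 and platelet factor Pf4 at 5.40 ± 0.12 and 6.93 ± 0.86, and passed with no filter on dim genes (0.0215) and with 1 array per animal (0.0464). The 14 stroma and endothelial genes had a median difference of 0.23 and passed fry (adjusted p = 7.75e-05) but not camera (adjusted p = 0.139). It passed camera without array 1 of animal 2 of the full-length mice (0.0425) or of both genotypes (0.0439), with an intensity trend and robust prior (0.0189), with the animal as a random block (0.0369) and with the mean of the probe sets (0.0320). With an estimated correlation the 4 lists did not pass in any setting where it was tried (smallest adjusted p = 0.530 for MHC class II, 0.455 for dendritic cell, 0.367 for megakaryocyte and 0.367 for stroma genes). The largest differences among stroma genes were those of Cxcl12 and, in the opposite direction, the matrix gene Dcn, at 7.50 ± 2.04 and 5.04 ± 0.36.

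The stem and progenitor list, with 19 measured genes, had a median difference of 0.22 (camera of limma, adjusted p = 0.496), with 10 genes higher and 9 lower in value. The progenitor antigens Cd34, at 4.03 ± 0.80 and 6.75 ± 1.03, and Prom1, at 3.99 ± 1.20 and 6.55 ± 0.27, had the largest differences. With a filter at the 75th percentile the list passed in the opposite direction (-0.60, adjusted p = 0.0239). The 11 eosinophil, basophil and mast cell genes had a median difference of 0.64 (adjusted p = 0.497) and passed with 1 array per animal (0.71, adjusted p = 0.00239). Cpa3, a mast cell carboxypeptidase, was at 8.66 ± 2.19 and 11.96 ± 0.05, with full-length arrays 2 and 3 of animal 2 at 11.84 and 11.91 and the other 2 at 7.11 and 6.90, and Siglecf, an eosinophil receptor, at 5.41 ± 2.87 and 8.44 ± 0.85. The 23 interferon-stimulated genes had a median difference of -0.07 (adjusted p = 0.414), with Oas3 at 6.47 ± 1.02 and 5.01 ± 0.62 and Isg20 at 9.63 ± 0.59 and 8.20 ± 0.26. The interferon list passed, with lower values, without full-length animal 1 (-0.63, adjusted p = 0.000741), without the 2 full-length arrays high in erythroid genes (-0.91, adjusted p = 2.44e-05) and without truncated animal 2 (-0.52, adjusted p = 0.0354). With an estimated correlation the stem and progenitor, the mast cell and eosinophil and the interferon lists did not pass in any setting where it was tried (smallest adjusted p = 0.457, 0.352 and 0.501). The 13 lists left of those tested had medians from -0.51 to 0.39, and none passed camera on the animal means (smallest adjusted p = 0.0675). They cover T cells, NK cells, genes that cooperate with the fusion, p53 targets, apoptosis, inflammation and glycolysis. The rest cover oxidative phosphorylation, cholesterol synthesis, protein stress, handling stress, RAS feedback and the Wnt and Notch responses. In other settings 5 of the 13 passed. Apoptosis genes did so with quantile normalization again, with either replicate block and with camera on ranks, among others. The remaining ones were RAS feedback, glycolysis, handling stress and the Wnt and Notch responses.

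Of the 31 lists tested with camera, 7 were higher and 2 lower in truncated animals, and 0 passed with an estimated correlation. The latter test rests on 2 residual degrees of freedom, so its outcome does not show that no list was shifted. Over 23 other settings repeated with an estimated correlation after the data were seen, lists passed in 1, where the 8 arrays were taken as independent and the monocyte and macrophage list passed (adjusted p = 0.0189). Splitting the animals by their number instead of by genotype gave 10 lists, so the preset correlation finds lists in animal differences of other kinds as well.

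Without the 2 full-length arrays high in erythroid genes, the differences of 54 genes named by the rule moved by under 1.5 times in 26. These include Cxcl12, Sphk1 and all but Mllt3 (-2.16) of the other top genes. The top genes had been chosen by their small p on all arrays, which favours genes that these 2 arrays do not move. Of the 54 differences, 18 became smaller, 5 became larger and 5 turned direction. Among the smaller were Ctsg (0.86), Cpa3 (0.083), Camp (2.08), Vcam1 (1.56), Mrc1 (1.59), Cxcr4 (1.45), Cd34 (1.51), Prom1 (1.03), Cd79b (0.76), Edem1 (0.29), H2-Oa (0.98), Trim10 (-0.92), Polr1b (-0.36), Isg20 (-0.69) and Cbfb (-0.0084), and the larger were Runx1 (-2.11), Oas3 (-2.56), Tcf4 (2.28), Pola1 (1.42) and Rrm2 (1.33). Those that turned were Siglecf (-1.26), Ank1 (1.07), Tnfrsf13c (0.26), Dcn (0.18) and Ube2c (0.28).

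Repeat arrays of an animal did not all lie close together. Array 1 of animal 2 correlated more with the array of animal 1 than with arrays 2 and 3 of its own animal, in both genotypes, as the plot of principal components shows. In full-length arrays Pearson's r across genes was 0.983 with the array of animal 1 and 0.870 with each of arrays 2 and 3, and in truncated arrays it was 0.980 and 0.944, with genes not being independent replicates. Arrays 2 and 3 of animal 2 correlated at 0.997 in each genotype. The median SD was 0.25 between animals of a genotype, 0.21 between the arrays of animal 2, and 0.06 (full-length) and 0.05 (truncated) between arrays 2 and 3. Averaging by the labels therefore mixes unlike arrays in animal 2, and the spread between animals, and with it the p-values, depends on whether these labels hold.

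**Figure D3:**
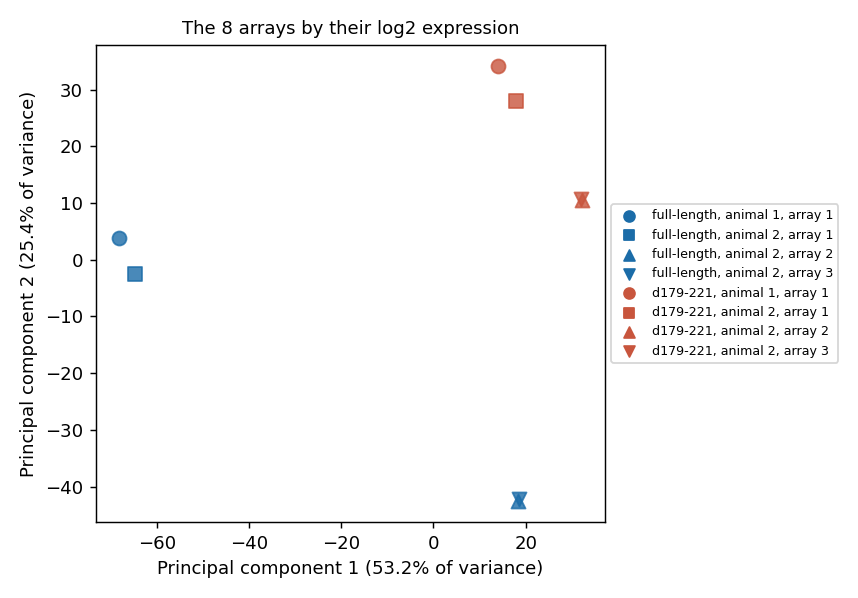
Principal components 1 and 2 of log2 expression (53.2% and 25.4% of the variance), 1 point per array, coloured by genotype and shaped by animal and array. In each genotype the array of animal 1 lies beside array 1 of animal 2, and arrays 2 and 3 of animal 2 lie together elsewhere.

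The Y-linked gene Eif2s3y lay between 8.45 and 8.99 in all 8 arrays, and Uty between 5.84 and 6.45, each by its brightest probe set. Kdm5d, also Y-linked, lay at 2.17 in full-length animal 1 and 2.23 in array 1 of full-length animal 2, at 6.22 and 6.28 in arrays 2 and 3 of that animal, and between 5.55 and 6.36 in the truncated arrays. Xist, the RNA of the inactive X chromosome, lay between 4.97 and 6.42 by its brightest probe set, and another of its probe sets lay at 5.93 and 4.61 in full-length animal 1 and array 1 of full-length animal 2 and between 3.09 and 3.43 in the other 6 arrays.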

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

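The weighing of the similarity of array 1 of animal 2 to animal 1, of the 2 full-length arrays high in erythroid genes and of dilution was tested only after those results were seen, as was the nearness of arrays in the spike-in controls, while the tests of spike-in controls that part the arrays, RNA quality, neighbouring genes and sample splits were set before their results. Of 144 sets of 4 arrays tested for a value far from the other 3, 2 held one. Chance gives about 1 in 20 for independent normal values. The arrays of a genotype lie in close pairs, so that rate does not apply here. The mitosis gene Birc5 was at 9.94 in array 1 of truncated animal 2 and between 9.55 and 9.59 in the other truncated arrays. The median of the stroma and endothelial genes was 5.44 in array 1 of full-length animal 2 and between 5.13 and 5.16 in the other full-length arrays.

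Array 1 of animal 2 resembled the array of animal 1 in each genotype. A processing batch shared by both genotypes would move the same genes in both, but the difference between these arrays and arrays 2 and 3 correlated at only 0.231 across genes between the genotypes. This argues against a shared batch as the whole cause, and a shared part stays open, since 574 genes parted these arrays from arrays 2 and 3 across both genotypes when arrays were taken as independent. Of 45 labelling and hybridisation control probe sets 3 (6.67%, where chance gives 2.86% for independent arrays) parted these 4 arrays from arrays 2 and 3. An animal label out of place in each genotype cannot be told apart from a real likeness, since the higher correlation in 2 of 2 genotypes is the pattern itself. Kdm5d parted the arrays by a wide gap in full-length mice (2.17 and 2.23 against 6.22 and 6.28). In truncated mice it did not (5.55 and 6.02 against 6.36 and 6.30), but a Y-linked gene cannot part mice of the same sex. The absence of a gap there thus does not count against a label out of place. The other probe sets of Kdm5d and those of Eif2s3y and Uty parted the arrays by under 1 log2 unit or not at all. Array 1 of animal 2 lay nearer to arrays 2 and 3 than to animal 1 in 42 of 45 control probe sets in full-length and 45 of 45 in truncated mice, with a median distance to animal 1 of 0.64 and 2.15 log2 units, but these controls follow the processing and not the animal the RNA came from.

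The higher granule and monocyte genes in truncated animals could rest on the 2 full-length arrays high in erythroid genes. Without these arrays only animal 2 is left among the full-length mice, by its arrays 2 and 3, which correlated at 0.997. Against that animal the median difference was still 1.42 for the secondary granule and 1.34 for the monocyte list. Before, these medians were 2.52 and 1.61. For the primary granule list the median went from 2.66 to 0.94. A comparison against 1 full-length animal cannot decide the question for the genotype. Dilution of leukemic by erythroid cells would lower these lists by the same amount only if all of them came from leukemic cells alone. Their medians in the 2 arrays, against arrays 2 and 3, spread over 3.21 log2 units. They ran from -3.55 for primary granule to -0.34 for monocyte genes. The monocyte list holds Vcam1, a gene of splenic macrophages and endothelium, and differences of dim genes are understated. The spread therefore cannot exclude dilution, which stays open. RNA quality stays open, although the 3' to 5' difference parted the genotypes in 0 of 2 control genes, Actb and Gapdh, since 1 array made the overlap for Actb. For Gapdh the full-length arrays lay between -0.19 and 0.05 and the truncated arrays at -0.19, -0.17, 0.27 and 0.28, so its overlap did not rest on 1 array. For Actb full-length animal 1 was at 0.81, the other full-length arrays at 0.33 to 0.38 and the truncated arrays at 0.46 to 1.02. The bound set beforehand, an overlap in both genes, was thus too weak to exclude it. A different stage or make-up of the leukemias, the mutagen and the age of the mice stay open, and none of these could be tested.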

How the results depend on the processing

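The grouping of arrays by best correlation and the omission of array 1 of animal 2, or of the 2 full-length arrays high in erythroid genes, were chosen after the data were seen, as was the estimated correlation in 23 other settings; the rest were planned. The counts of genes past an adjusted p of 0.05 (limma, 0 higher and 0 lower) were 2 and 1 with an intensity trend and robust prior, and 1 and 1 with a filter at the 75th percentile. They were 264 and 81 with the animal as a random block on 8 arrays, and 642 and 352 with the arrays taken as independent (p-values then too small). With 1 array per animal they were 1651 and 1355. That setting took array 1 of each animal by its label. These arrays correlate well within a genotype, and if a label is out of place the spread is too small. Under 0.10 the counts were 187 and 22. They were 0 and 0 in the added settings that keep 2 units in each genotype, and in the other settings that keep every animal and array, the replicate blocks apart. In the settings that leave 1 animal in a genotype, that animal is taken to vary like the others. The setting without the 2 full-length arrays high in erythroid genes is among them. With a replicate block the counts were 181 and 25 (animal number) and 586 and 357 (animal and array number). These numbers name different mice, the pairing has only 2 pairs, and same-numbered animals deviated with a correlation of 0.30. Leaving out an animal or array gave 0 to 440 higher and 0 to 206 lower genes. The 9 lists called were 7 to 13 elsewhere, except 0 with an estimated correlation and 2 with fry. Values that turned direction, none of them called before, were Runx1 with 1 array per animal (0.36), by its probe set with the largest variance (0.084) and on leaving out full-length animal 2 (0.23, within -1.20 to 0.23 over animals and arrays left out), and, without the 2 full-length arrays, Siglecf (-1.26), Ank1 (1.07), Tnfrsf13c (0.26), Dcn (0.18) and Ube2c (0.28). The called erythroid list turned to 0.46 without these arrays. Uncalled lists described singly that turned are given with their range on leaving out an animal or array, where that range holds both signs. They were MHC class II (-0.72 with 1 array per animal; -0.54 to 0.96), stem and progenitor (-0.60 with the 75th percentile, where it was called at adjusted p = 0.0239; 0.11 without the 2 arrays), mast cell and eosinophil (-0.44 without the 2 arrays; -0.10 to 0.77), megakaryocyte (-0.30 without the 2 arrays), interferon (-0.63 to 0.46), G1/S (-0.025 with 1 array per animal; -0.17 to 0.22) and G2/M (0.031 with the trend, with no filter and with the most variable probe set, 0.073 with 1 array per animal; -0.058 to 0.15), where the set test and not the median gives the direction. The cause was not tested. Of the 13 lists not described singly, 11 turned and 5 were called in some setting. The median SD between animals was 0.25, and 0.20 with no filter. Probe sets as their own units were not run for each named gene. Array values give no signal over background, and genes near 4.74 or below can understate differences.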

Other observations

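The genes of the first 2 paragraphs were chosen after their values were seen, while the tests of sample splits and of neighbouring genes were set before their results. Among the full-length arrays, some mast cell genes and some erythroid genes lay in opposite sets of arrays, with no test of the difference. Fcer1a, the alpha chain of the IgE receptor, was at 5.29 and 5.21 (log2) in the array of animal 1 and array 1 of animal 2, and at 12.39 and 12.47 in arrays 2 and 3 of animal 2. Cma1, a mast cell chymase, was at 4.91 and 5.13 in the former and 9.34 and 9.39 in the latter, and the stem cell factor receptor Kit at 7.46 and 7.74 against 10.36 and 10.35. The red cell anion exchanger Slc4a1 was at 11.88 and 11.62 in the former and at 6.06 or less in the latter, and the erythroid regulator Klf1 at 11.82 and 11.43 against 8.92 and 8.99. The inflammatory cytokine gene Il1b was at 8.43 and 8.48 in the former and 5.50 and 5.61 in the latter. Other mast cell genes did not follow, as the tryptase Tpsab1 was at 7.20 and 7.48 in the former and 6.51 and 6.45 in the latter, Ms4a2, the beta chain of the IgE receptor, lay between 11.28 and 11.50 in all 4 full-length arrays, and Hdc, the histamine-forming enzyme of basophils and mast cells, between 10.76 and 10.97.

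Among the truncated arrays, some antibody and antigen presentation genes parted arrays 2 and 3 of animal 2 from the rest, with no test of the difference. Jchain was at 10.85 and 10.81 in arrays 2 and 3 and at 3.56 and 3.32 in the array of animal 1 and array 1 of animal 2. Ighm was at 13.11 and 13.15 against 7.75 and 7.02, and Cd74, the invariant chain of MHC class II, at 11.67 and 11.71 against 8.83 and 8.80. H2-Oa, of the MHC class II list, lay the other way, at 7.34 and 7.28 against 7.88 and 7.99. Alas2, which makes heme in red cell precursors, was lower in arrays 2 and 3, at 8.40 and 8.35 against 11.18 and 11.34.

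Other splits of the samples were set against the genotypes. For the 4 animals, 209 genes passed an adjusted p of 0.10 between the genotypes and 0 in either other split, with 1 of 3 splits reaching 209, and 3 splits are too few for a share under 0.05. For the gene lists, 9 passed between the genotypes and 10 between animals 1 and animals 2, with 2 of 3 splits reaching 9, again too few for such a share. With the 8 arrays taken as independent, 994 genes passed an adjusted p of 0.05, a count reached by 1 of 35 splits. Arrays of an animal are not independent, so that share cannot be read as one of 35 equal chances, and only the 3 splits that kept the best-correlated pairs of arrays together gave any genes, again too few for a share under 0.05. The highest of the other splits, with 574 genes, parted the array of animal 1 and array 1 of animal 2 from arrays 2 and 3 of animal 2 in both genotypes, which points to a structure of the samples.

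A hypothesis that differences in strain background contribute to the genes with the smallest p was tested by gene order. Among the 100 genes with the smallest p, 3 neighbouring pairs were found, a count that a strain variant near the targeted locus or in the background would raise (Ms4a6b with Ms4a6d, Hopx with Spink2, and Clec4a2 with Clec4n), where 10000 random sets gave a median of 1 (permutation test, one-sided, p = 0.0595). The pairs lie on chromosomes 19, 5 and 6, so at most 1 of them can lie near the targeted locus. The test leaves the hypothesis open, as the count lies above the random median but within its range. Pairs of related genes can also be expressed in the same cells. A variant that acts on a single gene would add no pair, so the test cannot see it. Nnt, which C57BL/6J mice carry in a partly deleted form, was at 5.17 to 6.25 in full-length and at 8.23 to 8.88 in truncated arrays, and a difference in strain at Nnt was not tested.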
